A study of Mus musculus with 12 samples.

How the data were processed

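Liver RNA (top left lobe) of 12 C57BL/6J mice was extracted with RNeasy Plus Micro columns, with a minimum RNA integrity number of 9.0, and libraries were made with the NuGEN Ovation RNA-Seq v2 and Ultralow kits, per the labels' protocols. The first kit amplifies double-stranded cDNA and does not mark the strand of the RNA. The deposited table holds raw read counts per gene symbol: reads were aligned with STAR to mm10 and counted with featureCounts, per the submitters' processing notes, and versions, annotation and counting options are not given in the sources used here. The table has 25239 unique gene symbols, of which 5535 had no count in any library, and 0 mitochondrially encoded genes. Each column was matched to its sample by the animal code in the sample's description, and groups (chow or FPC-NASH, male or female, 3 separate mice each) were taken from the labels.

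Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with edgeR's filterByExpr by group, which left 14822 genes, library sizes were scaled by TMM (factors 0.877 to 1.18), and 1 model with a mean per group was fitted to all 12 libraries, so that the groups shared the estimate of the spread. Quasi-likelihood tests (glmQLFit and glmQLFTest, robust) gave the diet effect in males, the diet effect in females, the difference of males minus females on each diet, and the diet by sex interaction, which is the diet effect in males minus that in females. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05, and every adjusted p of a gene in the text comes from this edgeR test unless another tool is named. The SE of a gene's log2 fold change was computed from that change and the F statistic of its test. It is thus no measure of precision apart from the p-value. CPM values are counts per TMM-scaled library size, given as mean ± SD of 3 mice. With 3 mice against 3, the samples can be split in 10 ways, so no exact permutation test of a single value can fall below a p of 0.1 and none is used for single genes.

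Before the data were examined, 42 gene lists were fixed: 33 lists of liver pathways and cell type markers, tested with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and lists of technical, contamination and sex check genes, described by their members. Camera p-values were adjusted over the 33 lists of a comparison. The alternatives were camera with a correlation estimated per list and fry. Of 691 list members 637 were tested. The genes named were also chosen by a rule fixed before the data were examined. In each diet comparison it took the 10 largest rises and falls, in each sex comparison the 8 largest in each direction. It asked for an adjusted p under the threshold, a mean of at least 2 CPM and no overlap between the libraries of the groups (which chance gives in 1 of 10 splits), skipping provisional gene names. For the interaction they were the 10 largest in each direction without the overlap condition, and in each list up to 4 members with the smallest p. The text names a selection of the genes that this rule gave, made after their values were seen. A first selection had passed over Saa1, Lcn2, Sdhb, Spp1 and Fcer2a because their calls were lost in several alternatives, and they were put back, so the selection may still favour stable genes and the counts of calls kept in every alternative hold for the named genes only. Ass1, a urea cycle gene that the rule gives in females, was left out because its counts were far too few for a urea cycle gene in liver. Results for some of the genes taken by the rule are not reported here. Chromosome positions are those of GENCODE vM21 on GRCm38, the assembly that mm10 denotes.

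Alternatives fixed before the data were examined were DESeq2 1.42.0 (Wald test, its own size factors), RLE size factors in edgeR, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, and a fit of only the 6 libraries compared. Fits without any scaling factor were added after seeing the data. On simulated counts with the real means and library sizes, in which 100 genes were changed by 2-fold and 100 by 4-fold, edgeR recovered 97% of 4-fold and 77% of 2-fold changes for the diet effect in males among 14664 genes, with 4.40% false calls. It recovered 90% and 45% for the interaction among 14668 genes, with 5.59% false calls. False edgeR calls were 4.47% for the diet in females, 6.67% for the sexes on the FPC-NASH diet and 8.42% for the sexes on chow, above the threshold for both sex comparisons and for the interaction. DESeq2 made 14.7% false calls in the same simulated interaction. The simulation drew genes independently, with 1 mean over all groups and the spread of the trend by abundance, and it held no outlying livers. Far fewer genes changed in it than were called in the real diet and sex comparisons, so recovery in the real data may be lower. Each comparison was simulated once, with 8 to 16 false edgeR calls, so the false call rates are rough.

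The replicate numbers come from the labels, and nothing in them ties equal numbers to a shared litter, batch or day. Deviations from the group means of same-numbered livers correlated at -0.213 to 0.242 over the 18 pairs of livers, with 6 above 0.1. For chow males and chow females all 3 pairs lay above 0.1 (0.209, 0.198 and 0.153), so a pairing by number is possible there. The reported values of that comparison are unpaired. They were compared with those of the fit that took the replicate number as a block, with the same replicate effects in all 4 groups. No 2 replicates agreed within counting noise (the lowest chi-square per gene between replicates was 20.8). Depth was 42764883 to 48611194 counts per library, and counts of amplified libraries without molecular identifiers are not independent molecules, so counting error understates the spread. Sequence shared between genes was measured as the percentage of a gene's 75-base windows that occur in a GENCODE vM21 transcript of another gene, on either strand, an overlapping gene included.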

Results

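Gene expression was measured by RNA sequencing in the top left liver lobe of 12 C57BL/6J mice, an inbred laboratory strain. Male and female mice received either standard chow or the FPC-NASH diet, a chow replacement rich in fructose, palmitate and cholesterol that is used to evoke steatohepatitis (fatty liver with inflammation), for 16 weeks. Each of the 4 groups held 3 separate mice. The libraries held 42764883 to 48611194 counts assigned to genes, and the 10 most abundant genes took 15.5 to 20.2% of them. The sex-linked transcripts matched every label. Xist, the non-coding RNA of the inactive X chromosome, averaged 942 ± 243 CPM (SD, n = 3) in chow females and 0.959 ± 0.266 CPM in chow males. The Y-linked helicase gene Ddx3y averaged 88.6 ± 9.09 CPM in chow males and 0.0929 ± 0.0421 CPM in chow females. Replicates within a group correlated at Spearman's rho of 0.987 to 0.995 across genes, which are not independent. Livers separated by diet and sex on the first principal components, with FPC-NASH male 3 and chow male 1 nearer to each other than the rest of their groups.

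**Figure D1:**
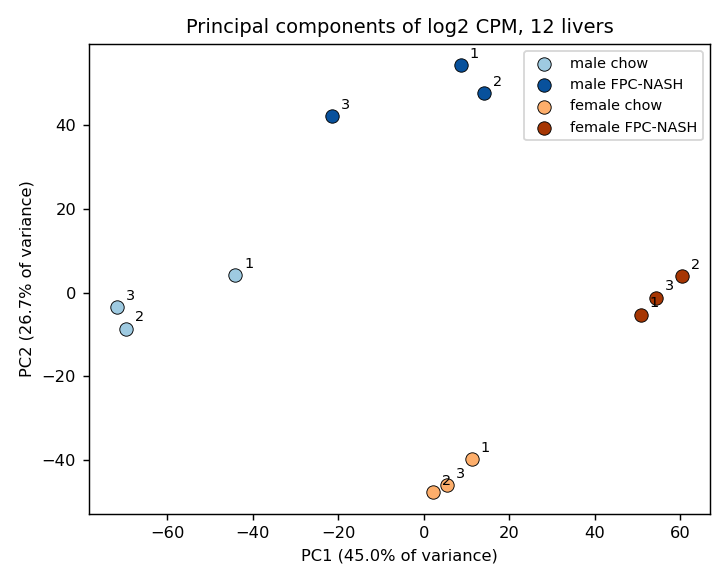
Principal component scores of the 12 livers from log2 CPM of the 14822 tested genes, with PC1 (45.0% of the variance) on the horizontal and PC2 (26.7%) on the vertical axis; each point is 1 liver, coloured by group and numbered by replicate. The 4 groups do not overlap, and FPC-NASH male 3 and chow male 1 lie between the other male livers.

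The first comparison asked what the FPC-NASH diet changed in male livers. Transcripts of cholesterol synthesis genes fell: Sqle, the squalene epoxidase gene (chromosome 15, 59315077 to 59331192 on GRCm38), went from 82.6 ± 35.0 CPM on chow to 2.64 ± 0.590 CPM (SD, n = 3), a log2 fold change of -4.97 (SE 0.40, adjusted p = 6.74e-05). Of the 22 cholesterol synthesis genes and SREBP2 targets, 19 fell, 0 rose and 3 did not pass (21 fell when adjusted over the list alone), among them Idi1 (-3.74), Cyp51 (-2.73) and Mvk (-2.04). Resident macrophage genes rose in the other direction, with Vsig4, a complement receptor of Kupffer cells (chromosome X, 96247203 to 96293438), at 8.04 ± 2.73 CPM on chow and 45.5 ± 4.40 CPM on the FPC-NASH diet (log2 fold change 2.4999, SE 0.19, adjusted p = 3.02e-05). Gpnmb, a marker of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), rose from 0.215 ± 0.0292 to 6.68 ± 4.04 CPM (log2 fold change 4.94, SE 0.68).

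In all, 1986 of the 14822 genes tested were higher and 1604 lower in FPC-NASH males at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 1027 rises and 281 falls exceeded 2-fold. Among the largest rises besides Gpnmb were those of Rad51b, a DNA repair gene (log2 fold change 5.61, SE 0.14), the serine synthesis gene Psat1 (5.14), the monocyte receptor gene Cd300e (4.68), the lipase gene Pnpla3 (4.55), the fasting hormone gene Fgf21 (4.38), the macrophage elastase gene Mmp12 (4.19) and Ly6d (4.14). Among the largest falls were those of Adgrf1 (-5.15), Lrtm1 (-5.14), Sqle, Raet1d (-4.60), Dct (-4.43), the drug-inducible cytochrome gene Cyp2b10 (-4.17) and the male-typical steroid dehydrogenase gene Hsd3b5 (-3.91). Adjusted p-values of the genes named for males did not exceed 0.0323, and standard errors lay between 0.11 and 1.23 on the log2 scale.

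Gene lists were compared with all other genes by camera, which called 22 of the 33 lists in males, 14 higher and 8 lower, with a preset correlation between genes. With a correlation estimated from these libraries no list was called in any comparison by camera, so the counts of members carry the description that follows. Splits that mixed the groups called up to 19 lists for the diet in males, but they keep part of the real difference and are not a pure chance level. Over all genes, in both directions together, 24.2% were called for the diet in males and 26.8% in females. The share was 29.5% between the sexes on chow, 32.7% on the FPC-NASH diet and 1.92% in the interaction. A count of members in 1 direction stands beside the genes called in that direction. Of the 14822 genes, 1986 were higher and 1604 lower for the diet in males, and 1828 and 2141 in females. Between males and females they were 2270 and 2101 on chow and 2762 and 2087 on the FPC-NASH diet. In the interaction 145 were positive and 140 negative. Counts of members near the share over all genes in the same direction are no result about a list. Kupffer cell markers rose in 13 of 14 (14 adjusted over the list alone), with Clec4f (2.02), Folr2 (2.29) and Csf1r (2.38) beside Vsig4. Kupffer genes in males had a camera adjusted p of 1.79e-12, and adjusted p = 0.209 with an estimated correlation. Of the 18 markers of recruited and lipid-associated macrophages 13 rose, such as the lysosomal Cd68 (2.31) and lipoprotein lipase, Lpl (3.04), while Fabp5, a fatty acid binding protein, fell by 2.21 on the log2 scale (15 rose and 1 fell adjusted over the list alone). Recruited macrophage genes in males had a camera adjusted p of 2.67e-07, and adjusted p = 0.285 with an estimated correlation. Neutrophil markers rose in 4 of 8 (6 adjusted over the list alone), with the colony-stimulating factor receptor gene Csf3r at 2.77. Neutrophil genes in males had a camera adjusted p of 0.00241, and adjusted p = 0.404 with an estimated correlation. Inflammatory cytokine and NF-kB genes rose in 15 of 24 (17 adjusted over the list alone), including Il1a (1.38), Tlr2 (2.22) and Nlrp3 (2.31). Inflammatory genes in males had a camera adjusted p of 5.06e-08, and adjusted p = 0.285 with an estimated correlation. Collagen and matrix genes rose in 6 of 28 (7 adjusted over the list alone), with Col15a1 at 1.41 and the growth factor gene Tgfb1 at 1.19. Matrix genes in males had a camera adjusted p of 1.06e-04, and adjusted p = 0.524 with an estimated correlation. Stellate cell markers rose in 1 of 15, endothelial markers in 2 of 15 and cholangiocyte markers in 0 of 14 (0, 1 and 0 adjusted over the list alone), and camera called none of these 3 lists, though it called the endothelial list with the replicate number as a block (0.0476), without the low-count filter (0.0407) and in 6 of the 12 fits without a single liver. Dendritic cell and MHC class II genes rose in 5 of 14 (7 adjusted over the list alone), B and plasma cell markers in 2 of 11 (likewise 2) and T and NK cell markers in 0 of 17 (likewise 0). Their camera calls in males had adjusted p of 6.64e-04, 0.0242 and 0.0115, and adjusted p = 0.507, 0.583 and 0.580 with an estimated correlation. Single livers weighed on these lists. The mean centred log2 CPM of dendritic genes was 0.078, -1.30 and -1.24 in chow males 1, 2 and 3. In FPC-NASH males 1, 2 and 3 it was 0.058, 1.26 and -0.070. For T and NK genes these values were 0.334, -1.40 and -1.23 on chow, and -0.098, 0.98 and -0.32 on the FPC-NASH diet.

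Transcripts of sterol efflux and fat handling genes changed as well. LXR targets rose in 6 of 11 (7 adjusted over the list alone), among them the paired sterol exporters Abcg5 (1.76) and Abcg8 (1.43) and the macrophage exporter Abcg1 (2.39). LXR genes in males had a camera adjusted p of 8.27e-04, and adjusted p = 0.209 with an estimated correlation. Fatty acid oxidation genes and PPARA targets rose in 14 of 24 and fell in 1 (likewise 14 and 1 adjusted over the list alone), with the peroxisomal enzyme gene Ehhadh at 2.05, Cyp4a14 at 1.95 and Vnn1 at 1.27. PPARA genes in males had a camera adjusted p of 7.28e-06, and adjusted p = 0.296 with an estimated correlation. Lipid droplet and uptake genes rose in 8 of 20 and fell in 1, including the fatty acid transporter Cd36 (1.70) and the droplet protein gene Cidea (3.30), with the same counts adjusted over the list alone. Lipid droplet genes in males had a camera adjusted p of 0.0198, and adjusted p = 0.310 with an estimated correlation. Hepatocyte identity genes fell in 8 of 18 (11 adjusted over the list alone), such as Arg1 (-0.79) and albumin, Alb (-0.61). Hepatocyte genes in males had a camera adjusted p of 1.23e-05, and adjusted p = 0.209 with an estimated correlation. Complement and coagulation genes fell in 11 of 24 (12 adjusted over the list alone), with coagulation factor XI, F11, at -1.87. Complement genes in males had a camera adjusted p of 3.47e-05, and adjusted p = 0.310 with an estimated correlation. Genes fixed beforehand as male-biased in liver fell in 11 of 20 and rose in 1 (14 and 1 adjusted over the list alone), among them Selenbp2 (-2.73), Susd4 (-2.11) and Serpina1e (-2.09). Male-biased genes in males had a camera adjusted p of 3.58e-06, and adjusted p = 0.285 with an estimated correlation. The female-biased list was not called (adjusted p = 0.623): 5 members rose, including Cyp2b9 (3.72) and Cyp2b13 (2.48), and 5 fell. Other lists were lower too. These were nuclear-encoded respiratory chain subunits, 8 of 24 lower with Ndufs3 at -0.49 and Sdhb at -0.56, xenobiotic genes of CAR and PXR, 9 of 20 lower with the carboxylesterase gene Ces2a at -1.40, and the periportal list, 7 of 12 lower with the growth hormone target Igf1 at -0.88. Their camera adjusted p-values were 2.72e-05, 0.00491 and 0.00116, and adjusted p = 0.524, 0.285 and 0.285 with an estimated correlation. Adjusted over the list alone 8, 9 and 8 members were lower and 0, 3 and 1 higher. Of the 20 acute phase genes 4 rose over all genes and 0 adjusted over the list alone, among them serum amyloid A, Saa1 (3.26, SE 0.90), and lipocalin 2, Lcn2 (3.39, SE 0.97). The replication licensing gene Mcm3 (0.98), the haem oxygenase gene Hmox1 (2.06) and the p53 target Eda2r (1.996) rose as well. These 3 are single members taken for their small p and do not stand for their lists. The mean centred log2 CPM of the cell cycle, NRF2 antioxidant and p53 lists changed in males by 0.47 (SE 0.32), 0.28 (SE 0.14) and 0.45 (SE 0.15). For cell cycle genes it was 0.48, 0.36 and -0.51 in FPC-NASH males 1, 2 and 3.

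The count of lower genes in males depended on single livers: it was 2556 without FPC-NASH male 3, 842 without FPC-NASH male 2, 992 without FPC-NASH male 1 and 917 without chow male 2, and it was 944 when only the 6 male libraries were fitted. Psat1 missed the threshold without chow male 3 (adjusted p = 0.0511), Hsd3b5 without FPC-NASH male 1 (0.0520) and Pnpla3 without chow male 1, 2 or 3 or FPC-NASH male 1 (0.0530 to 0.0942). The calls of Psat1, Pnpla3, Saa1, Lcn2, Fgf21, Ly6d and Mmp12 were not made by limma-voom, nor that of Saa1 with the replicate number as a block (0.0712), nor those of Pnpla3, Saa1 and Lcn2 without the low-count filter (0.0503, 0.0538 and 0.0598). The log2 fold change of Saa1 was 1.56 without FPC-NASH male 2 (adjusted p = 0.105), and that of Hsd3b5 was -6.66 without FPC-NASH male 3 and at the other end -3.38 without FPC-NASH male 2. Leaving out 1 liver also moved the folds of these other genes named for males by over 1.5 times, with log2 fold changes of Psat1 (3.64 to 5.57), Cd300e (3.64 to 5.62), Pnpla3 (3.55 to 5.39), Fgf21 (3.22 to 4.87), Ly6d (3.48 to 4.53), Cidea (2.61 to 4.17), Lcn2 (2.36 to 3.84), Cyp2b9 (3.05 to 4.04), Cyp2b13 (1.89 to 2.78) and Adgrf1 (-5.96 to -4.86). The calls of Saa1, Lcn2 and Sdhb were lost without 4, 5 and 3 of the 12 livers in turn (adjusted p up to 0.105, 0.113 and 0.0553).

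The same question was asked of the diet in female livers. Matrix genes rose broadly. Of these, 25 of the 28 collagen and extracellular matrix genes were higher on the FPC-NASH diet, 0 were lower and 3 did not pass (26 higher and 1 lower adjusted over the list alone). The basement membrane collagen Col4a1 (chromosome 8, 11198423 to 11312826) stood at 33.1 ± 2.57 CPM on chow and 87.1 ± 17.8 CPM (SD, n = 3; log2 fold change 1.39, SE 0.15, adjusted p = 1.65e-04). Hamp, which encodes the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), fell from 909 ± 98.6 to 185 ± 37.3 CPM (log2 fold change -2.30, SE 0.20, adjusted p = 4.97e-05). Cholesterol synthesis genes fell in 19 of 22 (20 adjusted over the list alone), with Sqle at -4.01, Idi1 at -3.93 and Cyp51 at -2.93 (camera adjusted p = 9.92e-11, and adjusted p = 0.255 with an estimated correlation; for the male list these were 7.40e-13 and 0.285).

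By edgeR's quasi-likelihood test, 1828 genes were higher and 2141 lower in FPC-NASH females, 821 and 260 of them by over 2-fold. The largest rise was that of Cfd, the complement factor D or adipsin gene, with 5 counts summed over the 3 chow females and 1185 over the 3 FPC-NASH females (log2 fold change 7.56, SE 1.21). Other large rises were those of Cidea (5.61, from 4 summed counts), Ly6d (5.56), the monoacylglycerol acyltransferase gene Mogat1 (4.77), Gpnmb (4.65), Themis (4.52), Mmp12 (4.42) and the heparan sulfate proteoglycan gene Gpc1 (4.33). Large falls were those of Adgrf1 (-4.17), the organic anion transporter gene Slco1a1 (-4.15), Sqle, Idi1, the energy homeostasis gene Enho (-3.84) and the sulfotransferase gene Sult3a1 (-3.48). For the genes named in females, adjusted p-values were at most 0.00808 and standard errors ran from 0.10 to 1.21.

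Camera called 21 lists in females, 14 higher and 7 lower. The matrix list (camera adjusted p = 2.00e-13, and adjusted p = 0.247 with an estimated correlation) included Col14a1 (0.97), Col15a1 (1.44) and Col4a2 (1.22). Stellate cell and myofibroblast markers rose in 3 of 15 (2 adjusted over the list alone), beside 1828 of 14822 over all genes. Among them were Tpm2 at 1.97 and the growth factor receptor Pdgfrb at 0.93. Stellate genes in females had a camera adjusted p of 0.00749, and adjusted p = 0.255 with an estimated correlation. Kupffer cell markers rose in 10 of 14, likewise adjusted over the list alone, with Adgre1 (1.82), Cd5l (1.56), Folr2 (1.19) and Vsig4 (0.88). Kupffer genes in females had a camera adjusted p of 2.14e-05, and adjusted p = 0.265 with an estimated correlation. Recruited macrophage markers rose in 14 of 18 (16 adjusted over the list alone), with Lpl at 3.00 and Cd68 at 1.44. Recruited macrophage genes in females had a camera adjusted p of 6.33e-09, and adjusted p = 0.247 with an estimated correlation. The neutrophil list rose in 5 of 8, with the lactoferrin gene Ltf going from 5 to 233 counts summed over 3 livers (5.24). Neutrophil genes in females had a camera adjusted p of 0.00749, and adjusted p = 0.424 with an estimated correlation. Inflammatory genes rose in 16 of 24 (18 adjusted over the list alone), with the monocyte chemokines Ccl2 (2.40) and Ccl7 (3.34) and the receptor Tlr2 (1.52). Inflammatory genes in females had a camera adjusted p of 5.07e-07, and adjusted p = 0.255 with an estimated correlation. No T, NK, B or plasma cell marker passed the test in females, and those lists were not called by camera. Dendritic cell genes rose in 1 of 14 in females (0 adjusted over the list alone; camera adjusted p = 0.0405, and adjusted p = 0.689 with an estimated correlation), a camera call that ended with RLE size factors (0.0536) and with the replicate number as a block (0.0519).

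Lipid droplet and uptake genes rose in 12 of 20 (13 rose and 1 fell adjusted over the list alone), with the droplet assembly gene Fitm1 (2.61), Cd36 (2.09), Fabp4 (1.34) and Cidec (3.66). Lipid droplet genes in females had a camera adjusted p of 4.33e-07, and adjusted p = 0.171 with an estimated correlation. PPARA targets rose in 13 of 24 and fell in 1 (16 and 2 adjusted over the list alone), with Acaa1b at 1.89, Ehhadh at 1.52 and Vnn1 at 1.44. PPARA genes in females had a camera adjusted p of 2.87e-06, and adjusted p = 0.255 with an estimated correlation. LXR targets rose in 6 of 11, likewise adjusted over the list alone, with Abcg1 (1.24) and Abcg5 (0.87). LXR genes in females had a camera adjusted p of 8.19e-04, and adjusted p = 0.211 with an estimated correlation. The desaturase Scd1 (2.48) and elongase Elovl5 (1.504) rose, while the fatty acid synthesis list as a whole was not called (adjusted p = 0.374). Hepatocyte identity genes fell in 9 of 18 (11 adjusted over the list alone), led by the urea cycle gene Cps1 (-1.48) and Alb (-0.73). Periportal genes fell in 8 of 12 (9 adjusted over the list alone), with Gls2 at -1.76 and Igf1 at -0.91. For hepatocyte and periportal genes camera gave adjusted p = 2.85e-05 and 2.85e-05, and both lists had adjusted p = 0.211 with an estimated correlation. Xenobiotic genes fell in 10 of 20, likewise adjusted over the list alone, with Cyp2c54 at -2.32 and Ces2a at -1.47. Complement and coagulation genes fell in 11 of 24 with 1 rise, such as F7 (-0.98) and, in the acute phase list, fibrinogen beta, Fgb (-0.68). For xenobiotic and complement genes camera gave adjusted p = 2.85e-05 and 2.96e-05, and adjusted p = 0.171 and 0.265 with an estimated correlation. The female-biased list fell in 9 of 23 and rose in 1 (10 and 1 adjusted over the list alone), with Cyp3a44 (-2.16) and Cyp2c69 (-1.49) beside Sult3a1. Female-biased genes in females had a camera adjusted p of 1.46e-04, and adjusted p = 0.255 with an estimated correlation. Male-biased genes went both ways in females, 6 higher, including the elongase gene Elovl3 (3.58) and Mup20 (1.02), and 4 lower, including Serpina1e (-1.05), and that list was not called (adjusted p = 0.645). The p53 targets Cdkn1a (2.48) and Ccng1 (0.71) rose with 5 of 15 list members. P53 genes in females had a camera adjusted p of 9.64e-05, and adjusted p = 0.214 with an estimated correlation. Keratin genes Krt8 (0.76) and Krt18 (0.63) and the glutathione synthesis gene Gclc (1.15) rose too. They are likewise single members taken for their small p. The mean centred log2 CPM of the cholangiocyte and NRF2 antioxidant lists changed in females by 0.43 (SE 0.35) and 0.22 (SE 0.14).

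In females the count of higher genes was 1154 without chow female 2, and that of lower genes was 1302 without chow female 2 and 1175 without FPC-NASH female 2. The calls of Cidea and Ltf, which rest on few chow counts, were not made by limma-voom. Folds named for females that moved by over 1.5 times without 1 liver were, as log2 fold changes, those of Cfd (7.004 to 8.21), Cidea (5.09 to 6.82), Ltf (4.63 to 6.74), Gpnmb (4.02 to 5.01), Mmp12 (3.28 to 4.85), Ccl7 (2.59 to 4.01), Ccl2 (1.73 to 2.71), Slc4a1 (2.56 to 4.01) and Slco1a1 (-4.56 to -3.48).

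Whether both sexes responded alike was asked next. Of the genes called in each sex, 995 were higher in both, against 245 for independent lists of those sizes, and 728 were lower in both, against 232; 50 were called in opposite directions. The 1723 shared genes took in Sqle, Idi1, Cyp51, Adgrf1, Alb and Igf1 among the falls and Gpnmb, Mmp12, Lpl, Cd68, Cd36, Ly6d, Abcg5, Ehhadh and Vnn1 among the rises. Log2 fold changes of the 2 sexes, which come from separate mice, correlated across genes with Pearson's r of 0.655 and Spearman's rho of 0.552, and genes are not independent replicates. Without chow female 2 the shared count was 1126.

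**Figure D2:**
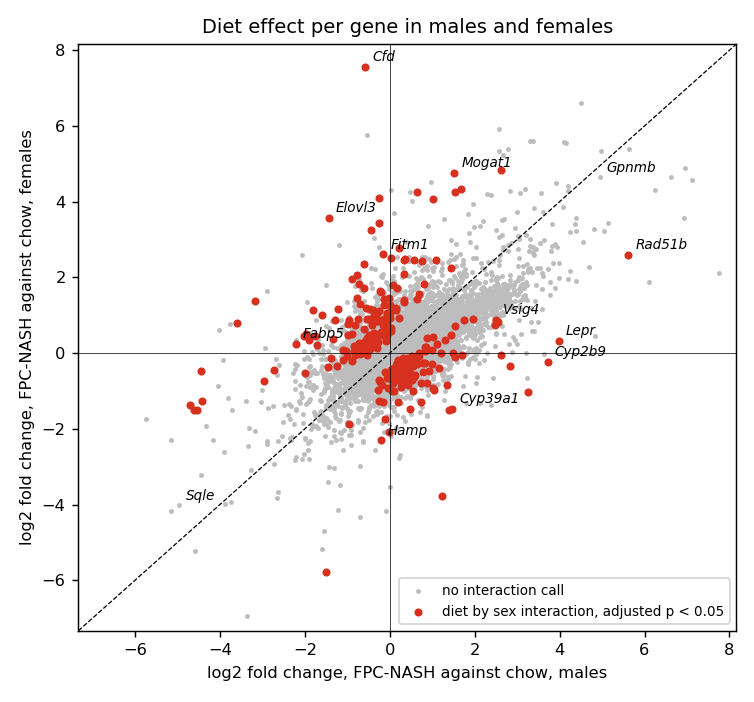
Log2 fold change of FPC-NASH against chow for each of the 14822 tested genes in males (horizontal axis) and females (vertical axis), each from 3 livers against 3; red points are the 285 genes whose diet effect differed between the sexes and the dashed line marks equal change. Sqle and Gpnmb lie near the line, whereas Hamp, Elovl3, Mogat1 and Cfd lie away from it on the female axis and Lepr and Cyp2b9 on the male axis.

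The diet by sex interaction tested the difference between the 2 diet effects directly. Kupffer cell markers leaned toward a larger rise in males. Vsig4 had an interaction of 1.62 (SE 0.26, adjusted p = 0.0172). Of the list 1 member passed over all genes and 12 of 14 passed adjusted over the list alone, with Clec4f at 1.10 (adjusted p = 0.0625; list median 1.12, camera adjusted p = 2.46e-08, and adjusted p = 0.614 with an estimated correlation). Collagen and matrix genes leaned the opposite way. Col4a1 had an interaction of -1.07 (SE 0.21, adjusted p = 0.0309). In all 1 of 28 passed over all genes and 12 adjusted over the list alone, and Col4a2 was at -0.85 (adjusted p = 0.0650; list median -0.60, camera adjusted p = 1.45e-07, and adjusted p = 0.950 with an estimated correlation). Hepcidin fell in females and was 492 ± 73.7 CPM on chow and 424 ± 113 CPM on the FPC-NASH diet in males (interaction 2.09, SE 0.28, adjusted p = 0.00551). The leptin receptor gene Lepr (chromosome 4, 101717404 to 101815352) rose in males, from 5.81 ± 1.02 to 91.7 ± 22.2 CPM, and was at 37.7 ± 14.1 and 47.3 ± 8.79 CPM in females (interaction 3.65, SE 0.38, adjusted p = 0.00290).

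In total 145 genes had a positive interaction, meaning a diet effect more positive in males, and 140 a negative one. Of these 285 genes, 67 were lower in females and not called in males, 65 higher in females and not called in males, 39 higher in males and not called in females, and 37 lower in males and not called in females. A further 27 rose in males and fell in females and 22 did the reverse. Among the largest positive interactions were those of Cyp2b9 (3.95), Lepr, Rad51b (3.01), which rose in both sexes, the oxysterol hydroxylase gene Cyp39a1 (2.92), Hamp, Ankrd9 (2.07), Pcp4l1 (1.94), the chemokine gene Ccl6 (1.75) and Pla2g7 (1.74). The largest negative ones were those of Cfd (-8.14), Elovl3 (-5.02), Tmem28 (-3.70), Clstn3 (-3.62), Mogat1 (-3.26), Dct (-3.16), Raet1d (-3.09), Slc15a5 (-2.95), Olig1 (-2.84) and Fitm1 (-2.76). Elovl3 fell in males, from 202 ± 45.9 to 74.7 ± 17.3 CPM, and rose in females, from 1.78 ± 0.962 to 21.4 ± 5.76 CPM. Lipid droplet genes Fitm1, Mogat1 and Fabp4 (-0.996) made 3 calls of 20 (8 adjusted over the list alone), all larger in females. Lipid droplet genes in the interaction had a camera adjusted p of 2.72e-05, and adjusted p = 0.428 with an estimated correlation. Male-biased genes gave 4 negative calls of 20 (10 negative and 1 positive adjusted over the list alone), with Elovl3, Selenbp2 (-2.28), complement C6 (-1.57) and Cyp2d9 (-0.96). Male-biased genes in the interaction had a camera adjusted p of 1.77e-08, and adjusted p = 0.484 with an estimated correlation. Female-biased genes gave 3 positive calls of 23 (9 positive and 1 negative adjusted over the list alone), among them those of Cyp2b9 and Cyp39a1. Female-biased genes in the interaction had a camera adjusted p of 2.42e-04, and adjusted p = 0.690 with an estimated correlation. Fabp5 fell in males and did not pass in females (interaction -2.46, adjusted p = 0.00182), and Abcg5 (0.89) and Cyp4a14 (1.06) rose more in males. Camera also called the B and plasma cell list (median 1.26, adjusted p = 0.0163, and adjusted p = 0.991 with an estimated correlation), the cholangiocyte list (median -0.49, adjusted p = 0.0148 and 0.991) and the respiratory chain list (median -0.13, adjusted p = 0.0270 and 0.991), in which 0, 0 and 0 members passed over all genes. The mean centred log2 CPM of B and plasma cell genes was uneven on chow. It was 0.0085, -1.59 and -0.67 in chow males 1, 2 and 3, and 1.33, -0.25 and 0.12 in chow females 1, 2 and 3. Fcer2a was at 2.59, Krt8 at -0.51 and Sdha at -0.20, all 3 short of the threshold.

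Interaction counts moved most between fits: DESeq2 called 453 and 471 genes in the same directions, leaving out FPC-NASH male 3 gave 294 and 431, and leaving out 1 other liver gave 31 to 144 positive and 30 to 175 negative calls. Of the 28 named interactions that passed, 13 passed in every alternative. Abcg5, C6, Ccl6, Cfd, Col4a1, Cyp2d9, Cyp4a14, Dct, Fabp4, Mogat1, Pcp4l1, Pla2g7, Selenbp2, Slc15a5 and Tmem28 each missed the threshold when at least 2 of the 12 livers were left out in turn (adjusted p up to 0.119, for Dct). With the replicate number as a block Ccl6 (0.0550), Cfd (0.0510), Abcg5 (0.0570) and Cyp4a14 (0.0571) missed it too, and Col4a2 passed (0.0480). Ccl6, Pla2g7, Cfd, Tmem28, Mogat1 and Dct were not called by limma-voom, nor Cfd (0.0532) and Dct (0.0591) without the low-count filter. Without 1 liver the interactions of Cfd (-9.37 to -7.48) and Cyp2b9 (3.28 to 4.24) moved by over 1.5 times once turned back from the log2 scale.

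**Figure D3:**
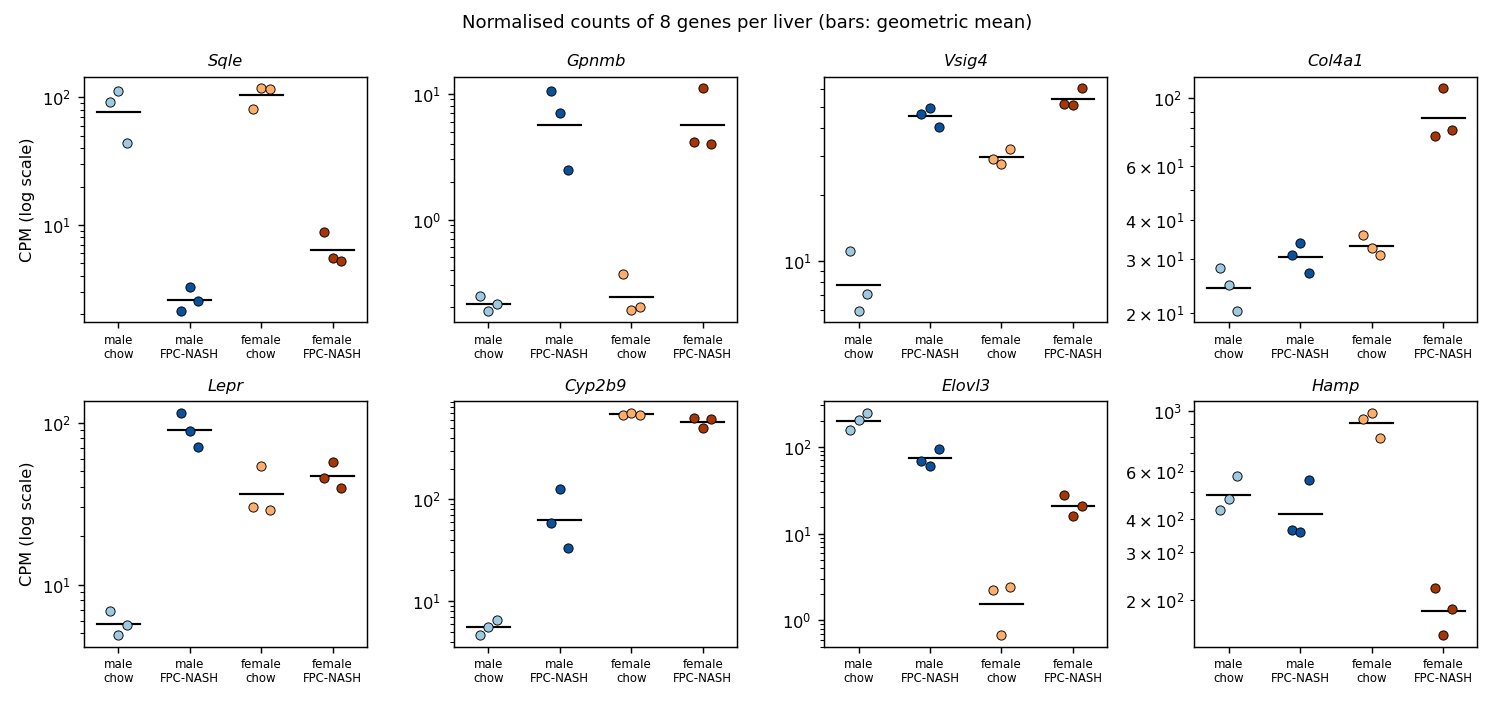
Normalised counts (CPM, log scale on the vertical axis) of 8 genes in the 12 livers, grouped by sex and diet on the horizontal axis; points are livers and bars geometric means of 3. Sqle falls and Gpnmb rises on the FPC-NASH diet in both sexes, Vsig4 starts lower in chow males, Col4a1 is highest in FPC-NASH females, and Lepr, Cyp2b9, Elovl3 and Hamp differ in their diet effect between the sexes.

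On chow, the comparison of males with females described the starting point. Male livers held more of the known male-typical transcripts. The fatty acid hydroxylase gene Cyp4a12a (chromosome 4, 115299046 to 115332815) averaged 364 ± 118 CPM in males and 0.389 ± 0.223 CPM in females (log2 fold change 9.88, SE 0.48, adjusted p = 8.53e-07). Alongside it were Cyp4a12b (9.43), Hsd3b5 (8.27), Elovl3 (6.82), the urinary protein gene Mup20 (6.32) and Cyp2d9 (4.94). Females held more of the sulfotransferases Sult3a1 (-10.43), Sult2a2 (-10.12) and Sult2a1 (-10.09), with 47 Sult2a1 counts over the 3 chow males and 55245 over the 3 chow females, and of A1bg (-8.98). Kupffer cell markers were lower in males: 12 of 14 (14 adjusted over the list alone), with Vsig4 at -1.88, Folr2 at -1.28 and Clec4f at -1.17. Kupffer genes on chow had a camera adjusted p of 9.68e-07, and adjusted p = 0.550 with an estimated correlation.

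Males had 2270 genes higher and 2101 lower than females on chow, 252 and 675 of them by over 2-fold, and adjusted p-values of the genes named were at most 0.0390 with standard errors of 0.10 to 1.29. The male-biased list was higher in 18 of 20 (19 adjusted over the list alone; Gstp1 3.50, C6 4.17) and the female-biased list lower in all 23 tested members (Cyp2b13 -8.58, Cyp2c69 -3.91, the prolactin receptor Prlr -2.002). Both sex-biased lists had camera adjusted p = 6.41e-21, and adjusted p = 0.0522 with an estimated correlation. Endothelial markers were lower in males in 12 of 15 (14 adjusted over the list alone), with the sinusoidal scavenger receptor Stab2 at -0.93 and the cadherin Cdh5 at -0.81. Endothelial genes on chow had a camera adjusted p of 6.66e-05, and adjusted p = 0.799 with an estimated correlation. Matrix genes were lower in 11 of 28 (15 adjusted over the list alone), with Thbs2 at -1.205 and Col15a1 at -1.003. B cell markers were lower in 3 of 11 (6 adjusted over the list alone), with Cd22 at -1.64 and the low-affinity IgE receptor gene Fcer2a at -1.47. Single livers weighed on the B cell list too. Its mean centred log2 CPM was 0.0085, -1.59 and -0.67 in chow males 1, 2 and 3. In chow females 1, 2 and 3 it was 1.33, -0.25 and 0.12, so chow male 1 lay above chow female 2. For matrix and B cell genes camera gave adjusted p = 4.57e-05 and 0.0110, and adjusted p = 0.847 for both with an estimated correlation. Interferon-stimulated genes were lower in 7 of 20 (Ifi27l2a -1.03) and inflammatory genes in 4 of 24 (Il1rn -2.05), with camera adjusted p = 0.0108 and 0.0110, and adjusted p = 0.878 for both with an estimated correlation. Respiratory chain subunits were higher in males in 13 of 24 (15 adjusted over the list alone), with Ndufa4 at 0.60 and Cox7a2 at 0.58. Respiratory chain genes on chow had a camera adjusted p of 1.10e-05, and adjusted p = 0.847 with an estimated correlation. Lipid droplet genes were higher in 6 of 20 and lower in 1 (8 and 1 adjusted over the list alone), with Fitm1 at 2.69, Fabp4 at 0.60 and the lipoprotein receptor gene Vldlr at -1.99. Lipid droplet genes on chow had a camera adjusted p of 0.0110, and adjusted p = 0.550 with an estimated correlation. The oestrogen receptor gene Esr1 (-2.17) was lower in males, and the oxysterol hydroxylase Cyp7b1 (3.49) and Slco1a1 (3.62) were higher. The count of genes higher in males was 1482 without chow female 1, and that of lower genes was 1309 without chow male 2 and 1345 without chow female 1. Folds on chow that moved by over 1.5 times without 1 liver were, as log2 fold changes, those of Sult2a1 (-10.69 to -9.86), A1bg (-9.31 to -8.32) and Slco1a1 (3.21 to 4.30). Fcer2a missed the threshold without 7 of the 12 livers in turn (adjusted p up to 0.156) and with the replicate number as a block (0.0502).

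On the FPC-NASH diet the same comparison asked how the sexes then differed. Matrix genes were lower in males in 25 of 28 (26 adjusted over the list alone), with Col4a1 at 30.4 ± 3.38 CPM in males and 87.1 ± 17.8 CPM in females (log2 fold change -1.52, SE 0.15, adjusted p = 6.42e-05), Col5a1 at -1.28 and Col14a1 at -0.99. Matrix genes on the FPC-NASH diet had a camera adjusted p of 2.20e-13, and adjusted p = 0.392 with an estimated correlation. Stellate cell markers were lower in males in 10 of 15, likewise adjusted over the list alone, with Reln at -1.02 and Pdgfrb at -0.92. The same held for endothelial markers in 6 of 15 (7 adjusted over the list alone), with Stab2 at -0.91 and Plvap at -0.68, and cholangiocyte markers in 4 of 14 (8 adjusted over the list alone), with Prom1 at -3.26 and Epcam at -1.87. Their camera adjusted p-values were 1.52e-04, 0.00388 and 0.00269, and adjusted p = 0.306, 0.966 and 0.966 with an estimated correlation. Of the Kupffer cell markers, 0 were higher and 0 lower at an adjusted p under 0.05 by edgeR; Vsig4 was at -0.26 (SE 0.18, adjusted p = 0.285) and Adgre1 at -0.64 (adjusted p = 0.128; called with the replicate number as a block, 0.0497, and without chow male 1, 0.0411), and the list median was 0.00 (camera adjusted p = 0.830).

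Males had 2762 genes higher and 2087 lower than females on this diet, 263 and 757 by over 2-fold. Sex-typical genes again showed large differences: Cyp4a12b (7.33), Cyp4a12a (7.27), Hsd3b5 (6.96), Slco1a1 (6.54) and Mup20 (5.90) were higher in males, and Sult2a2 (-9.15), Sult2a1 (-9.09), A1bg (-9.04), Sult3a1 (-8.13) and Cyp2b13 (-6.27) lower. The male-biased list was higher in 17 of 20 (18 adjusted over the list alone), with Cyp2d9 at 3.98, Gstp1 at 2.57 and C6 at 2.59. The female-biased list was lower in 21 of 23 and higher in 1 (22 and 1 adjusted over the list alone), with Cyp2c69 at -3.15 and Prlr at -2.34. For these sex-biased lists camera gave adjusted p = 6.39e-13 and 1.20e-15, and adjusted p = 0.206 and 0.124 with an estimated correlation. Fabp5 (-2.05), Mogat1 (-2.09), Vldlr (-1.73), osteopontin, Spp1 (-1.90), the bile acid reductase Akr1d1 (-1.199) and Cdkn1a (-1.51) were lower in males, and Hamp (1.2004), Cyp7b1 (2.504) and Ndufa4 (0.49) higher. Respiratory chain subunits were higher in 7 of 24 and interferon-stimulated genes lower in 2 of 20, with camera adjusted p = 0.0318 and 0.0471, and adjusted p = 0.966 for both with an estimated correlation; with RLE size factors the interferon call ended (adjusted p = 0.0610), as it did with the replicate number as a block (0.0805). Between the 2 diets, 1378 genes were higher and 934 lower in males on both, against 423 and 296 for independent lists. The count of genes higher in FPC-NASH males was 1827 without FPC-NASH female 2 and 1761 when only these 6 libraries were fitted, and the Hsd3b5 call was not made by limma-voom, its log2 fold change being 4.20 without FPC-NASH male 3 and 7.49 without FPC-NASH male 2. Without 1 liver the folds of Sult2a2 (-9.62 to -7.99), Sult2a1 (-9.56 to -7.65), Cyp2b13 (-6.86 to -5.98) and Prom1 (-3.91 to -2.96) moved by over 1.5 times too (log2 fold changes). Spp1 missed the threshold without FPC-NASH male 3 (adjusted p = 0.0540) or FPC-NASH female 2 (0.0533).

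**Figure D4:**
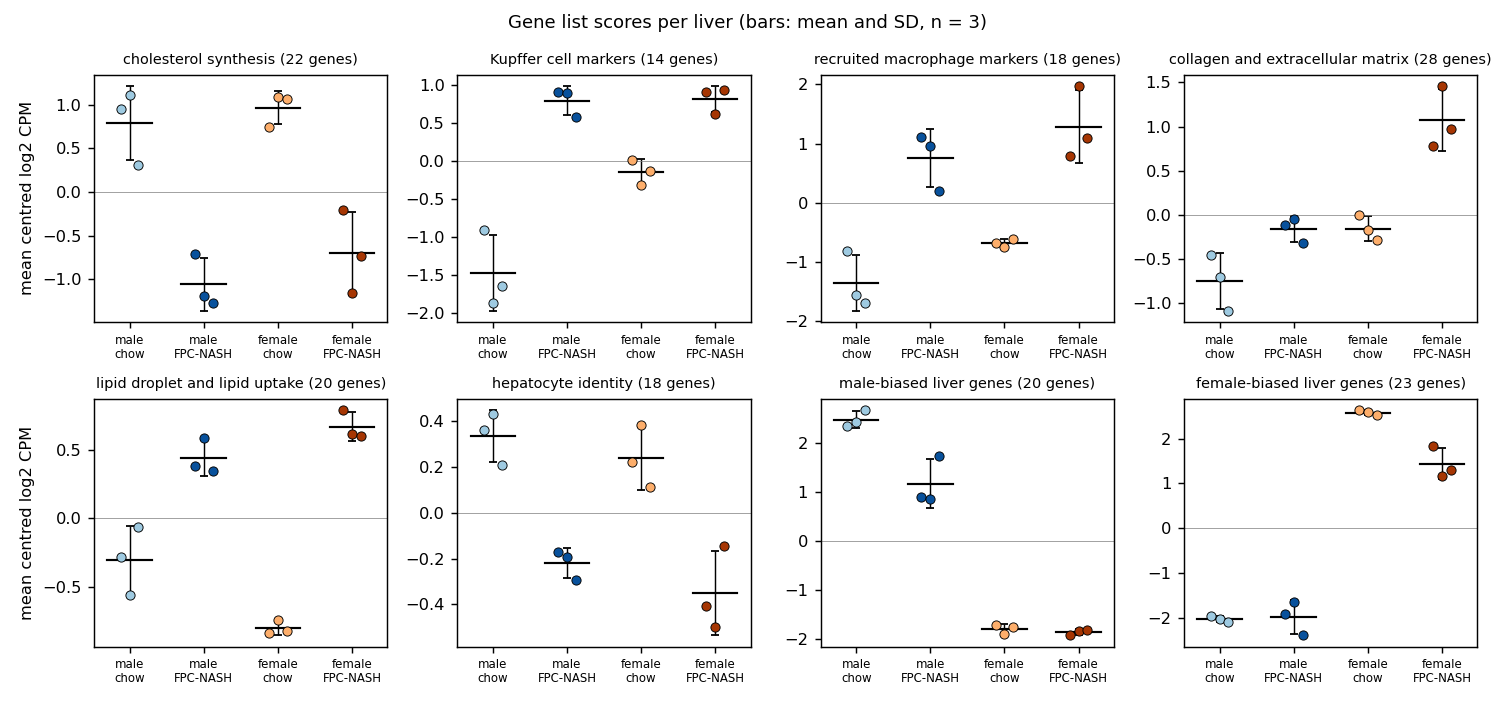
Mean centred log2 CPM of the members of 8 fixed gene lists (vertical axis) in each of the 12 livers, grouped by sex and diet (horizontal axis), with bars for the mean and SD of 3 livers. Cholesterol synthesis genes lie lower on the FPC-NASH diet in both sexes, Kupffer cell markers are lowest in chow males, and matrix genes are highest in FPC-NASH females.

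Several named genes share sequence with other genes, so that their counts are uncertain. Windows of 75 bases that also occur in another gene's transcripts, on either strand, made up 47.2% of Sult2a2, 47.1% of Folr2, 44.1% of Raet1d, 43.6% of Mup20, 42.6% of Cyp2c69, 41.3% of Cyp4a12b, 40.8% of Cyp4a12a, 32.3% of Acaa1b, 29.2% of Gstp1, 27.6% of Selenbp2, 23.6% of Idi1, 23.5% of Krt8, 19.7% of Serpina1e, 19.4% of Sult2a1, 18.5% of Saa1, 17.5% of Gpc1, 16.4% of Cyp2b13, 14.1% of Cyp2c54, 13.9% of Csf1r, 12.9% of Cyp2d9, 12.2% of Ndufs3, 11.7% of Hsd3b5, 11.4% of Ces2a, 11.1% of Xist and 11.02% of Cyp3a44. The library kit does not mark strand, so reads from an exon stretch that overlaps a gene on the opposite strand could not be told from the neighbour's. Apart from Folr2, Gpc1 and Csf1r above, such stretches were a small part of most named genes with a neighbour of this kind, with shared windows of 8.45% for Mogat1, 3.90% for Fitm1, 2.07% for Cyp51, 0.325% for Abcg5, 0.236% for Abcg8 and 0% for Col4a1, Col4a2 and Elovl3.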

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

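The comparisons of list scores, the sex-check shares, the splits and the median without scaling factors in this part were chosen after the results were seen, unlike the interaction test, camera and the fits without single livers, and the bound of 2.5 SE for setting an explanation aside was raised from 2 SE after the values were known. A diet effect that differed between males and females, by the interaction test of edgeR, set apart the genes and lists that follow, each with its interaction on the log2 scale (positive where the effect was more positive in males). Among genes these were Cyp2b9 (3.95), Lepr (3.65), Rad51b (3.01), Cyp39a1 (2.92), Hamp (2.09), Ankrd9 (2.07), Pcp4l1 (1.94), Ccl6 (1.75), Pla2g7 (1.74), Vsig4 (1.62), Cyp4a14 (1.06) and Abcg5 (0.89) on the positive side. On the negative side were Cyp2d9 (-0.96), Fabp4 (-0.996), Col4a1 (-1.07), C6 (-1.57), Alas2 (-2.22), Selenbp2 (-2.28), Fabp5 (-2.46), Gpc1 (-2.65), Fitm1 (-2.76), Olig1 (-2.84), Slc15a5 (-2.95), Raet1d (-3.09), Dct (-3.16), Mogat1 (-3.26), Clstn3 (-3.62), Tmem28 (-3.70), Elovl3 (-5.02) and Cfd (-8.14). Among lists, the median interaction was -0.60 for collagen and matrix genes, 1.12 for Kupffer cell markers, 1.26 for B and plasma cell markers, -0.49 for cholangiocyte markers, -0.39 for lipid droplet genes, -0.13 for respiratory chain subunits, -0.997 for male-biased and 0.78 for female-biased genes. No test of single outlying livers was made, and each group held only 3.

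Kupffer cell markers leaned toward a larger rise in males, from a lower level in chow males, with 1 of 14 members past the threshold over all genes and an adjusted p of 0.614 for the list with an estimated correlation. A lower share of hepatocytes in FPC-NASH males would raise the markers of every other cell type alike, but the Kupffer score exceeded the mean of the stellate, endothelial and cholangiocyte scores by 1.49 in the interaction (SE 0.36), which argues against it. A single liver does not carry the pattern, since the median interaction nearest to 0 was 0.96, without chow male 2. Without scaling factors the list median was 1.13. The median interaction of all genes hardly moved either, from 0.047 with TMM to 0.054, so that fit cannot decide about the scaling. Of the other immune lists, B and plasma, T and NK and dendritic cells had score interactions of 1.17, 0.70 and 0.66, and recruited macrophages and neutrophils 0.15 (SE 0.53) and 0.38 (SE 0.98). The Kupffer score exceeded the mean of the B, T and dendritic scores by 0.46 (SE 0.45), so fewer lymphoid and dendritic cells as well in chow males cannot be told from a change in Kupffer cells alone.

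Collagen and matrix genes leaned toward a larger rise in females, with 1 of 28 members past the threshold over all genes, an adjusted p of 0.950 for the list with an estimated correlation and a score interaction of -0.64 (SE 0.30). A lower hepatocyte share in FPC-NASH females would raise the other cell types too, and it stays open, because the matrix score differed from the mean of the endothelial and cholangiocyte scores by -0.46 with an SE of 0.28. Without FPC-NASH female 2, the liver with the highest matrix score, the median interaction was still -0.49, the nearest to 0 of the 12 fits. A larger number of stellate cells in FPC-NASH females cannot be told from more matrix transcripts per cell either, because the matrix score differed from the stellate score by -0.45 (SE 0.20), a difference that the first bound of 2 SE would have counted against this explanation. The stellate score itself had an interaction of -0.19 (SE 0.18), and no biological mechanism was tested.

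Sex-biased genes leaned toward each other, male-biased genes falling more in males and female-biased genes more in females, with 4 of 20 and 3 of 23 members past the interaction threshold over all genes and adjusted p = 0.484 and 0.690 with an estimated correlation. RNA of the other sex in the libraries would need a share of 35.3% male RNA in FPC-NASH females and 49.0% female RNA in FPC-NASH males for the median falls, while Y-linked counts allowed at most 0.0787% and Xist counts 0.0761%. A general loss of hepatocyte transcripts stays open as a cause. The interaction of the male-biased score minus that of hepatocyte identity genes was -1.28 (SE 0.39) and that of the female-biased score 1.15 (SE 0.31). Members near the count floor in the other sex could hardly fall there, so these differences cannot decide. Chow females held Cyp4a12a at 0.389 CPM, and chow males held Sult2a1 at 0.380 CPM. Reads shared among the Cyp2b, Cyp2c, Sult and Mup families were not resolved and stay open. Without FPC-NASH female 2 the female-biased median was 0.52, and over the 12 fits it reached 1.14, while the male-biased median ran from -0.82, without FPC-NASH male 2, to -1.44.

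Whether chance alone could give these counts was asked by splitting the same livers in other ways. For each diet or sex comparison there are 10 splits of the 6 livers, too few for a share under 0.05. A mixed split keeps part of the real difference between its groups and the rest as spread within them. Its counts are thus not a pure chance level, and few gene calls follow in part from the construction. The real split called 3590 genes for the diet in males, 3969 for the diet in females, 4849 between the sexes on the FPC-NASH diet and 4371 on chow, 1 of 10 splits in each case reached this, and the highest other split called 0. The splits took no account of replicate numbers, on chow too. For the count of lists called by camera the real and the highest other values were 22 and 19 for the diet in males (1 of 10 splits as high), 21 and 22 for the diet in females (3 of 10), 8 and 19 for the sexes on the FPC-NASH diet (10 of 10) and 14 and 18 on chow (4 of 10). For the interaction, 100 regroupings of the residuals of the additive model were tested with limma on log2 CPM. The real grouping called 302 genes and the highest other 13, so that 1 of 100 reached it. That is the smallest share that 100 regroupings can give. Mixed regroupings hold any real interaction as spread, which lowers their calls, so chance is not excluded by this count of genes. The count of lists called in the interaction was 8, and 85 of the 100 regroupings gave as many, up to 22. These regroupings can keep part of a real interaction too, so they do not show what chance alone gives. No list was called with an estimated correlation, so a list call by the preset correlation alone is weak evidence in these data.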

How the results depend on the processing

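Fits without scaling factors were chosen after the results were seen, and all others were fixed before the data were examined. Across the fits that kept all 12 libraries (DESeq2, RLE factors, limma-voom, filters, replicate block), counts of genes called in the diet and sex comparisons stayed within 1.5 times the reported ones, and no named gene changed sign while called. Exceptions were fits of only the 6 libraries compared, with 944 genes lower for the diet in males and 1761 higher in males on the FPC-NASH diet, where the smaller number of residual degrees of freedom is part of the construction, and DESeq2 for the interaction, with 453 genes higher and 471 lower. Its cause was not tested, though DESeq2 made more false calls than edgeR on simulated interactions. Camera with an estimated correlation called 0 lists in every comparison, and at an unadjusted p under 0.05 it gave 4, 6, 3, 3 and 2 for the diet in males, the diet in females, the sexes on the FPC-NASH diet, the sexes on chow and the interaction. Fry called 16, 17, 5, 11 and 3 lists in the same order.

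Leaving out each library in turn gave, for genes higher and lower, 1324 to 2180 and 842 to 2556 (diet in males), 1154 to 2239 and 1175 to 2146 (diet in females), 1827 to 2795 and 1540 to 2150 (sexes on the FPC-NASH diet), 1482 to 2758 and 1309 to 2321 (sexes on chow), and 31 to 294 and 30 to 431 (interaction). The upper ends came mostly without FPC-NASH male 3. Lists called ranged over 19 to 23, 18 to 21, 6 to 11, 11 to 16 and 6 to 13 in the same order, and the shared diet response over 1126 to 2145. The neutrophil list of the interaction, not called with all libraries, was called in the other direction without FPC-NASH female 1 (adjusted p = 0.0213) and reached 0.993 without FPC-NASH male 1.

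Without scaling factors the median log2 fold change of all genes moved to 0.21 in males and 0.18 in females for the diet and to -0.15 for the sexes on chow. Higher genes were then 87.8% of the calls in males (with TMM 55.3%), 84.7% in females (46.1%), 37.5% for the sexes on the FPC-NASH diet (57.0%) and 31.1% on chow (51.9%). The counts were 4106 higher and 572 lower in males, 3548 and 642 in females, 1535 higher on the FPC-NASH diet and 1272 higher on chow. All changes are thus relative to the bulk of genes.

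With the replicate number as a block the counts were 1934 higher and 1603 lower (diet in males), 1838 and 2065 (diet in females), 2679 and 2142 (sexes on the FPC-NASH diet), 2228 and 2123 (sexes on chow), and 129 and 145 (interaction). Of the 18 livers' pairings 8 fitted best with their own number. With 3 candidate partners each, several such matches arise by chance, so this count is at most a weak hint. The chow comparison was the only one with all 3 same-numbered pairs above 0.1. There the block added a call of the ER and integrated stress list (adjusted p = 0.0266) and ended that of Fcer2a (0.0502). The block also ended the calls of Saa1 (0.0712, diet in males) and of Ccl6 (0.0550), Cfd (0.0510), Abcg5 (0.0570) and Cyp4a14 (0.0571) in the interaction, which holds the same chow livers. It added those of Col4a2 (0.0480, interaction) and Adgre1 (0.0497, sexes on the FPC-NASH diet). Of lists, it ended dendritic and NRF2 genes in females (0.0519 each) and interferon genes between the sexes on the FPC-NASH diet (0.0805), and added endothelial markers for the diet in males (0.0476).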

Other observations

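The counts of widened and narrowed sex differences in this part, and Plin1 and Car3, were chosen after the results were seen. The fixed lists of clock genes, immediate early genes and other tissues were described by their members only. In females the clock genes fell in 5 of 16 and rose in 2, and in males they fell in 3 and rose in 1. Immediate early genes rose in 3 of 17 in females and in 3 in males. Over all 14822 genes, 2141 fell and 1828 rose in females, and 1604 fell and 1986 rose in males. The red cell membrane gene Slc4a1 (3.55, from 18 to 245 counts summed over 3 livers) rose in FPC-NASH females, as did Alas2, which makes haem in red cells and stood 3.35 higher in chow males than in chow females on the log2 scale (diet effect in females 1.45). In males the 2 genes did not move together. Alas2 stood at 119 ± 15.4 CPM on chow and 69.8 ± 16.0 CPM on the FPC-NASH diet, while Slc4a1 had 15 and 124 summed counts. The globin genes themselves were close to absent from the counts in all 12 livers: Hba-a1 had 6 counts in FPC-NASH males and 0 in FPC-NASH females, and Hba-a2, Hbb-bs and Hbb-bt were at 0. Of the 75-base windows of Hba-a2, 84.6% also occur in another gene's transcripts, and of Hbb-bs 51.5%. A share of that size need not empty a gene, as Sult2a2, at 47.2%, averaged 398 CPM in chow females. The cause of the missing globin counts was not tested. Of the fat cell genes, Adipoq had 4 counts in chow females and 0 in FPC-NASH females and Plin1 0 and 1. Among the 3 fat cell genes with enough counts for a test, 2 rose in females (3 adjusted over the list alone), Cfd and Cidec (3.66), and Car3 stood at 1105 ± 55.9 CPM on chow and 2019 ± 745 CPM on the FPC-NASH diet; in males 1 rose and 1 fell, with Car3 at 3345 ± 649 and 1372 ± 589 CPM.

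The sex difference was not narrowed by the diet across the interaction genes as a whole. Of the 285 genes, the difference between males and females was smaller on the FPC-NASH diet for 138 and larger for 147. It was called on chow alone for 100, on the FPC-NASH diet alone for 109 and on both for 76, of which 46 had opposite directions on the 2 diets.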
